A study of Homo sapiens with 6 samples.

How the data were processed

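Reduced representation bisulfite sequencing was carried out on 6 libraries of M07e, a cell line from an acute megakaryoblastic leukemia that is grown with GM-CSF. Per the labels, 3 libraries came from control cells and 3 from cells in which DNMT3B, a de novo DNA methyltransferase, had been knocked out with CRISPR. Per the labels' protocols, DNA was cut with MspI, ligated to methylated adapters, converted with bisulfite and amplified, so that the fragments read lie mostly in CpG-rich sequence. The labels do not say whether replicates came from separate cultures or clones, so any spread between them may be technical.

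The submitters' processing notes name FastQC, Trimmomatic, Bismark, HISAT2, methylKit and the genome build hg38, without versions, roles or an order. The program that made the table of regions is not given in the sources used here. The authors' deposited table holds 35130 regions. Per the file headers, each region has a p-value from a Mann-Whitney test, a p-value from a 2-dimensional Kolmogorov-Smirnov test and a q-value, all as the authors deposited them. The authors deposited the methylation level of each group as a percent, 1 mean per group and region, together with the mean difference in percentage points and the number of CpG sites. Levels of single libraries, read counts and coverage were not analysed here, so the depth is unknown. No value below has a replicate error, and the file does not say which points entered the authors' tests. Many of the authors' p-values are smaller than 3 libraries against 3 can give in a rank test, so points other than whole libraries, such as sites, must have been counted, and these p-values do not measure the spread between libraries.

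One group column is named M07e_WT and was taken as the control. The other is named M07e_3883, a name that no label uses, and was taken as the DNMT3B knockout because that is the only other genotype of the study. Every direction stated below rests on that reading. The deposited difference equals the M07e_3883 mean minus the M07e_WT mean within 0.01 points in all but 274 regions, of which 245 have under 5 sites and 1 was called. Starts and ends are printed 1-based on hg38. All 114 single-site regions span 1 base in the file's own half-open count, but the base from which the authors' input was counted could not be checked without a genome.

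The design written before the data were examined allowed for a table that holds only the authors' comparison, and in that case set no new test per region. A region was called when the authors' q was under 0.01 and the absolute difference at least 25 points. How the authors derived q is not given. It can lie close to the Kolmogorov-Smirnov p: 1.4e-11 for a p of 3.83e-12 at the MNX1 region of 44 sites, and 0.00925 for a p of 0.00269 at HLF. A q under 0.01 is therefore not read here as an error rate over all regions. Benjamini-Hochberg adjustment of that p called fewer regions, as given below. Regions were assigned to every RefSeq gene (GRCh38.p14, the same build) whose span they overlap, and otherwise to the nearest gene within 50000 bases, which covered 31777 regions and 12309 genes. The annotation used here gives gene starts and ends without strand or exons. The planned promoter, exon and intron classes were therefore replaced by regions within 1000 bases of either end of a gene (gene boundary), other regions inside genes (gene interior) and the rest (intergenic). Classes, chromosomes and 15 gene lists were compared with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment within each family. All 283 symbols listed by name were found in the annotation. The HOX, protocadherin and zinc finger lists take every symbol that starts with the family's letters and a digit, so they also hold pseudogenes, antisense RNAs, readthroughs and a few genes of other families. A version with protein-coding members that are not readthroughs was added after seeing the data. Shares have exact (Clopper-Pearson) 95% binomial intervals that describe the regions of the table and not the spread between libraries.

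The lists and the rule for named genes were fixed before the data were examined. The rule takes the 10 called regions with the largest loss and the 10 with the largest gain near a protein-coding gene (1 per gene), up to 3 genes per list, the 5 genes with the most called regions (ties by symbol), and DNMT3B, CBFA2T3, GLIS2, GATA1, ERG, RUNX1 and KIT. Alternatives covered the difference and q thresholds, the adjustment, the chromosomes, merging of called regions within 1000 bases, the boundary width and the assignment to genes. Several more were chosen after seeing the data, among them a comparison of each list with 10000 random lists matched on the number of regions per gene, a permutation of list membership within bins of that number. Adjusted exact p-values in the text are from Fisher's exact test. The list tests were tested on simulated data over the 12309 genes: in 20 draws with 40 genes called at 5 times the usual rate, both the Fisher's exact test and the matched lists found the list in 20, and in draws with no effect each found it in 1 of 20. The draws took random genes and called regions independently. They do not cover lists whose genes share regions or have many, smaller lists, or weaker effects. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.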

Results

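DNA methylation was compared between DNMT3B knockout and control M07e cells, with 3 libraries in each group, to find regions whose methylation differs. All levels, differences and q-values given here are values of the authors' deposited table, which has 1 mean per group, so the depth and the spread between the 3 libraries of a group are unknown. The column read as the knockout carries a name that no label uses, and all directions depend on that reading. The 35130 regions cover 3234 kilobases, of which 34008 regions lie on autosomes and 1112 on X. A region had a median of 6 CpG sites (quartiles 5 and 9) over 57 bases (quartiles 31 and 114).

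In the authors' deposited table the median region had a methylation level of 30.9% in the knockout and 7.59% in the control. The median difference was 17.4 points higher in the knockout (95% interval over regions 16.9 to 18.0), with 24036 regions higher and 11094 lower. No test between libraries was possible. Of all regions, 7348 (20.9%) had a control mean of exactly 0 and a knockout mean between 25% and 33.3%, and none of them was called. In the mirrored position, knockout at 0 and control between 25% and 33.3%, there were 795. With both kinds left out, a choice made after seeing the data, the median difference was 4.17 points; leaving out more regions on the higher side lowers the median by construction.

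**Figure D1:**
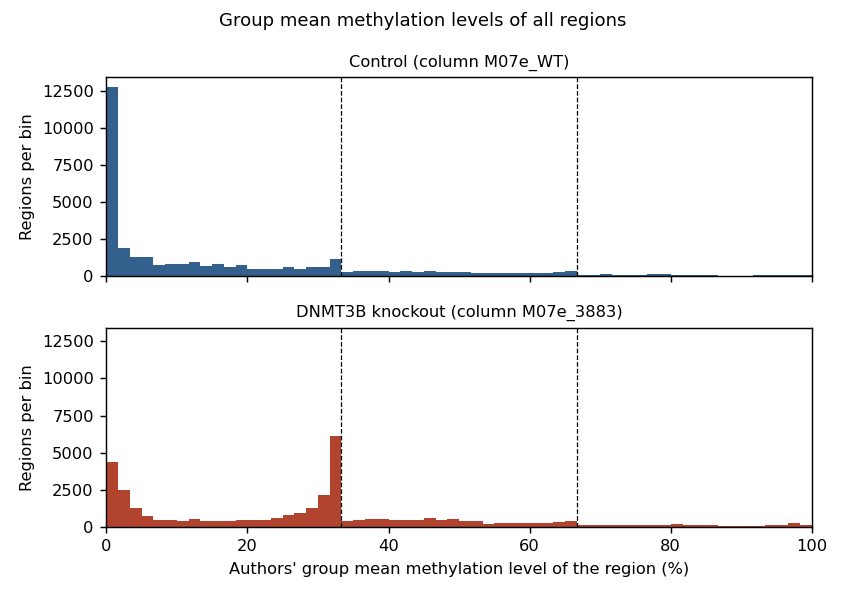
Number of regions (y axis) by group mean methylation level in percent (x axis, bins of 1.67 points) for the control and the knockout columns; dashed lines mark 33.3% and 66.7%. In the knockout 7985 regions lie within 3 points below 33.3% and 729 within 3 points above it, and in the control 1688 and 552.

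At the called threshold, methylation moved in both directions. Of 2368 called regions, 1606 were higher in the knockout (67.8%, 95% interval 65.9 to 69.7) and 762 lower (32.2%, 30.3 to 34.1). Called higher regions went from a median of 15.8% in the control to 62.0% in the knockout, and called lower regions from 58.1% to 14.9%. The column name behind this direction is not tied to a genotype by any label.

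The largest losses were at single short regions near PDPN, which encodes podoplanin, and within PDGFA, a platelet-derived growth factor subunit. At PDPN the level went from 96.1% in the control to 11.4% in the knockout over 10 sites (chromosome 1, 13583152 to 13583181, 576 bases from the gene, q = 2.48e-09). At PDGFA it went from 97.2% to 12.5% over 8 sites (chromosome 7, 501155 to 501224, inside the gene, q = 2.07e-07). A region inside BMP3, a bone morphogenetic protein gene, went from 76.3% to 0.693% (chromosome 4, 81030849 to 81030870, q = 2.43e-06). The HOXA10-HOXA9 readthrough locus had a region 2331 bases away that went from 88.0% to 14.2% (chromosome 7, 27160024 to 27160107, q = 0.000134). The other losses among the 10 largest were inside SPTBN4 (96.1% to 16.4%), which also held 1 called higher region, CRTAC1 (89.5% to 14.8%) and ACSL6 (91.9% to 18.6%), and outside the nearest genes JAKMIP2 (96.9% to 13.3%, 29701 bases away), TACC3 (90.8% to 13.3%, 22044 bases away) and MACF1 (92.5% to 18.2%, 2310 bases away), which also had 1 called higher region.

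The largest gain was inside FSCN2, a fascin of photoreceptors, from 5.0% in the control to 92.5% in the knockout over 8 sites (chromosome 17, 81519604 to 81519633, q = 7.07e-09). A region 591 bases from CDH2, which encodes N-cadherin, went from 13.5% to 98.7% (chromosome 18, 28177721 to 28177731, q = 0.00031). A region 644 bases from SRC, a tyrosine kinase gene, went from 11.1% to 91.1% (chromosome 20, 37406694 to 37406700, q = 3.08e-06). The remaining gains were inside TOP1MT (12% to 97.3%), CPLX3 (12.2% to 97.4%), MYO16 (6.67% to 90.7%) and ASTN2 (14.3% to 96.5%), and outside the nearest genes SKIDA1 (12.5% to 98.6%, 13123 bases away), MYCL (12.2% to 97.8%, 20574 bases away) and TRIM56 (16.7% to 97.9%, 6086 bases away). For these gains and the largest losses, a low group mean may be too low if sites not covered in some libraries were entered as 0. That possibility stays open, as weighed at the end.

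**Figure D2:**
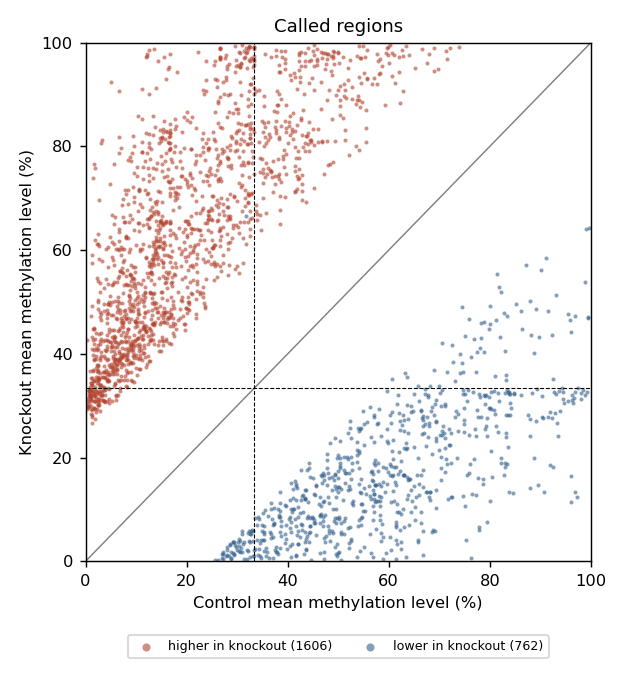
Knockout (y axis) against control (x axis) group mean methylation level in percent for each called region; dashed lines mark 33.3%. The 1606 regions higher in the knockout lie above the diagonal and the 762 lower ones below it, except 1 lower region whose deposited difference is not the difference of its group means, and 123 of the lower ones had a knockout mean within 6.67 points below 33.3% against 20 within 6.67 points above.

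Several genes held called regions of both directions. MNX1, a homeobox gene, had 7 called among its 17 regions, 2 lower and 5 higher. Its called region with the most sites, 44 across an annotated end of the gene (157010663), went from 77.0% in the control to 25.5% in the knockout (chromosome 7, 157010554 to 157010723, q = 1.4e-11), while 25 sites inside the gene at 157009857 to 157010056 went from 1.33% to 31.0% (q = 0.00874), a knockout mean just below 33.3%, where means of the table pile up. PTPRN2 had 7 called among 79 regions (3 lower, 4 higher), UNCX 6 of 26 (2 lower, 4 higher), CASZ1 5 of 38 (2 lower, 3 higher) and CBX8, a Polycomb protein gene, 5 of 12 (1 lower, 4 higher). The called regions assigned to CBX8 all lay outside the gene, 1255 to 15738 bases away. Some of those assigned to MNX1, UNCX and CASZ1 did too, up to 22822, 38753 and 39351 bases away. CASZ1 and CBX8 are 2 of 9 genes with exactly 5 called regions, named first by symbol; the others are EFNA2, EN1, ONECUT3, PRDM16, PCDHGA1, PCDHGA2 and PCDHGA3. In all, 1903 of 12309 genes had a called region, 700 a lower one, 1361 a higher one and 158 both.

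**Figure D3:**
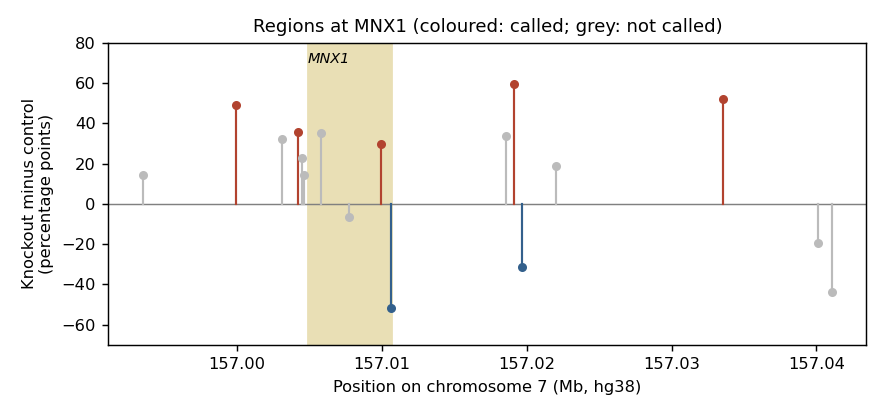
Difference in methylation, knockout minus control, in percentage points (y axis) for each of the 17 regions assigned to MNX1, by position on chromosome 7 in Mb (x axis); the shaded band is the gene. Coloured points are the 7 called regions, 5 above 0 and 2 below, and grey points were not called.

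DNMT3B, the fusion partners and the other genes fixed by name held few called regions in the authors' deposited table. At DNMT3B itself none of 3 regions was called, and methylation at these sites does not show whether the gene was edited. CBFA2T3, the 5' partner of the fusion in the study's title, had 1 called among 28 regions, from 15.4% in the control to 83.4% in the knockout over 13 sites (chromosome 16, 88941220 to 88941252, q = 4.52e-06). None of 5 regions at GLIS2, the other partner, was called, and the one with the lowest q was at 15.3% in the control and 1.53% in the knockout (q = 0.0012, under the difference threshold). None was called at ERG (2 regions), RUNX1 (3) or KIT (1), and GATA1 had no region in the table.

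Called regions lay near the ends of genes more often than the rest. Of the called regions 52.5% (95% interval 50.5 to 54.5) were within 1000 bases of a gene end, against 41.3% of those not called (odds ratio 1.57, adjusted exact p = 1.87e-25). With backgrounds chosen after seeing the data, the odds ratio was 1.32 against regions not called without the 7348 at 0 in the control, of which 27.0% were near a gene end, 2.55 against regions not called that differed by at least 25 points, and 2.24 against the latter without those 7348. Gene interiors held 34.8% against 42.3% (adjusted exact p = 9.32e-13) and intergenic sequence 12.8% against 16.4% (adjusted exact p = 1.8e-06). Lower and higher regions did not differ in any class (adjusted exact p = 0.722, 0.722 and 0.843). Called regions were also denser in CpG, with a median of 20.7 sites per 100 bases among lower, 17.9 among higher and 12.3 among regions not called. Their median lengths were similar (53.5, 61 and 57 bases), but they held more sites (medians 10, 11 and 6). A region with more sites may reach a low q more easily, so the calling itself may give this difference. The regions not called also include the 7348, with a median of 10.1 sites per 100 bases. Chromosomes 8 (8.70% called, adjusted exact p = 0.0317) and 10 (8.49%, adjusted exact p = 0.0317) held more called regions than the rest, and chromosomes 16 (5.09%, adjusted exact p = 0.023) and X (4.41%, adjusted exact p = 0.023) fewer. No chromosome differed in direction, the lowest adjusted exact p being 0.0881 for chromosome 14.

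Among the fixed lists, HOX, developmental signalling and tumor suppressor genes held called regions more often than other genes, counted over genes. Of 40 measured genes with HOX cluster symbols, most of them positional identity factors, 18 had a called region (45.0%) against 15.4% of other genes (odds ratio 4.51, adjusted exact p = 6.51e-05). Their 22 called regions, 8 lower and 14 higher, included HOXC11 (17.7% in the control to 83.4% in the knockout, 7051 bases from the gene) and HOXB2 (10.5% to 71.6%), beside the loss at HOXA10-HOXA9. The 40 include 4 antisense or readthrough genes, 3 of them with a called region, and without these 15 of 36 had one (odds ratio 3.93, adjusted exact p = 0.000716). Of 42 BMP, WNT, NOTCH and hedgehog signalling genes, 17 had a called region (odds ratio 3.74, adjusted exact p = 0.000405), with 8 regions lower and 17 higher. They included DLL1 (8.33% to 77.4%, 33141 bases from the gene), WNT5A (31.3% to 98.4%) and GLI2 (26.2% to 84.5%), but GLI2 also had 2 called losses (67.0% to 24.8% and 71.4% to 36.5%). Other losses, chosen after their values were seen, were at BMPR1A (53.9% to 6.91%, q = 3.4e-12) and HES5 (62.2% to 5.95%, 211 bases from the gene). Of 23 tumor suppressor genes often methylated in leukemia, 9 had a called region (odds ratio 3.53, adjusted exact p = 0.0193), with 5 regions lower and 12 higher, among them ESR1 (24.3% to 81.4%), TP73 (13.6% to 66.9%, 713 bases from the gene, with a called loss from 40.3% to 8.10% elsewhere) and SFRP1 (18.3% to 70.9%). Losses chosen after their values were seen include ID4 (49.2% to 7.84%, q = 1.05e-07) and SFRP2 (52.5% to 3.85%, 2116 bases from the gene). These lists hold genes with many regions: against lists matched on the number of regions, chosen after seeing the data, none of the 3 passed (adjusted permutation p = 0.144, 0.359 and 0.884 in the order given). Before adjustment over the 15 lists the permutation p for HOX genes was 0.0096, with 18 genes against a matched mean of 10.6. The permutation p-values given later for other homeobox genes were not adjusted over lists. Over distinct regions the signalling genes did not pass (odds ratio 1.74, adjusted exact p = 0.0752), while the HOX and tumor suppressor genes did (odds ratios 2.16 and 2.33, adjusted exact p = 0.0206 for each). HOX genes no longer passed over regions without the antisense and readthrough genes (odds ratio 1.96, adjusted exact p = 0.0688). That version held 19 called regions. It dropped the one near HOXA10-HOXA9, because a region outside genes was assigned to 1 gene only, here the readthrough. The change therefore rests partly on the assignment.

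The protocadherin list passed over genes but not over regions. Of 43 measured genes with clustered protocadherin symbols, most of them neuronal adhesion protein genes, 21 had a called region (odds ratio 5.27, adjusted exact p = 4.23e-06), and 20 of the 41 that are protein-coding. These genes overlap one another, and only 6 distinct regions of 45 were called, 3 lower and 3 higher (Fisher's exact test over regions, adjusted exact p = 0.311). PCDHGA1, PCDHGA2 and PCDHGA3, whose spans overlap, shared the same 5 called regions, 3 lower and 2 higher. The largest gain among these went from 23.8% in the control to 90.8% in the knockout (chromosome 5, 141389257 to 141389274, q = 0.00319) and the largest loss from 87.6% to 28.2% (141430942 to 141431002, q = 1.85e-06).

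Lists of blood cell genes did not pass at the main threshold. Counted over genes, the lymphoid list did at a difference of at least 10 points (odds ratio 6.12, adjusted exact p = 0.0176) and of at least 40 points (odds ratio 7.38, adjusted exact p = 0.0199), and the erythroid list at 40 points (odds ratio 4.92, adjusted exact p = 0.0461). At the main threshold both lists also failed against matched lists (adjusted permutation p = 0.884 for each) and over distinct regions (adjusted exact p = 0.311 for each). Of 15 megakaryocyte and platelet genes 3 had a called region (adjusted exact p = 0.896): GP9, a platelet glycoprotein gene (17.3% in the control to 67.8% in the knockout), MEIS1 (14.4% to 57.2%, 8599 bases from the gene) and THBS1 (40.7% to 5.75%). Of 13 erythroid genes 4 did (adjusted exact p = 0.275), among them the membrane skeleton genes ANK1 (2.56% to 63.1%, with a called loss from 43.5% to 13.8% over 35 other sites) and EPB42 (75.9% to 24.3%), and LMO2 (4.62% to 50.04%). Of 19 genes of the CBFA2T3-GLIS2 signature 6 did (adjusted exact p = 0.254), including HPSE2 (77.9% to 6.67%) and BMP4 (43.2% to 90.1%) beside CBFA2T3. Of 10 lymphoid genes 4 did (adjusted exact p = 0.165), including the T-cell factors BCL11B (8.33% to 68.8%, 1353 bases from the gene) and TCF7 (20.8% to 72.6%) and the kinase LCK (75.7% to 33.0%). Of 15 monocyte and granulocyte genes 2 did (adjusted exact p = 1), ELANE (80.2% to 32.7%) and CEBPA (6.74% to 32.8%, 308 bases from the gene). Of 14 stem and progenitor cell genes 2 did (adjusted exact p = 1), HLF (24.5% to 79.8%) and MN1 (45.8% to 95.7%).

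The other lists did not pass either. All 5 called regions of 26 imprinted genes were higher in the knockout, among them ZIM2 (14.6% to 63.9%, 9222 bases from the gene), IGF2 (15.4% to 57.6%) and GRB10 (10.0% to 46.0%), but neither the count (adjusted exact p = 0.799) nor the direction (p = 0.18, adjusted exact p = 1, Fisher's exact test) differed from other genes, and 5 regions are too few for the direction test to pass after adjustment. Of 405 genes with ZNF symbols, most of them C2H2 zinc finger genes, 58 had a called region (adjusted exact p = 0.799), among them ZNF516 (11.1% to 78.9%), ZNF782 (96.7% to 31.5%) and ZNF723 (8.41% to 71.6%). Of the 339 that are protein-coding and not readthroughs 47 did (adjusted exact p = 0.67). Of 11 germline genes 1 did (adjusted exact p = 1), DDX4 (42.6% to 98.3%, 4598 bases from the gene), and of 8 housekeeping genes 2 did (adjusted exact p = 0.596), RPL13A (32.7% to 92.0%, 635 bases from the gene) and ACTB (34.0% to 4.05%, 24882 bases from the gene). None of 16 DNA methylation machinery genes did (46 regions, adjusted exact p = 0.292). No list differed from other genes in direction (adjusted exact p = 1 for each), but only the 4 lists with at least 17 called regions (HOX, zinc finger, tumor suppressor and signalling genes) could have passed in either direction. The 4 lists with 6 or 7 called regions could have passed only toward losses, and the 7 lists with 5 or fewer, imprinted genes among them, could not have passed in either direction. Among the list genes named, 1 of the group means lies within 3 points below 33.3%, where means of the table pile up, for LCK, ELANE, CEBPA and ZNF782 (the knockout mean) and for WNT5A and RPL13A (the control mean).

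With Benjamini-Hochberg adjustment of the authors' Kolmogorov-Smirnov p, the number of called regions of a list could differ between adjustment over the list and over all regions, and did so for 5 lists. Adjusted over the list alone, the called regions numbered 20 for HOX genes (16 with the same p adjusted over all regions, 22 by the authors' q), 22 for the signalling genes (18 and 25), 14 for tumor suppressors (10 and 17), 6 for protocadherins (4 and 6) and 7 for the CBFA2T3-GLIS2 signature (6 and 7). For the other lists both adjustments gave the same number: 28 for zinc fingers (58 by the authors' q), 5 for lymphoid (6), 4 for erythroid (6), 3 for imprinted (5), 2 for megakaryocyte (3), 2 for monocyte and granulocyte (2), 1 for stem and progenitor (4), 1 for germline (1), 1 for housekeeping (2) and 0 for methylation machinery genes (0).

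**Figure D4:**
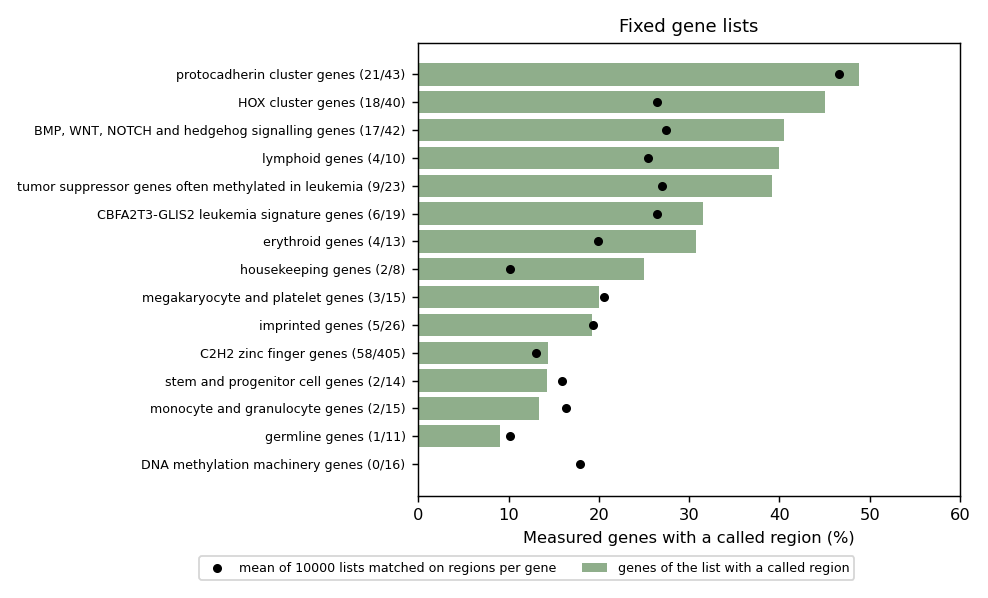
Percent of the measured genes of each fixed list (the HOX, protocadherin and zinc finger lists by symbol, noncoding genes included) with a called region (bars, x axis), with the counts beside each list's name (y axis); points give the mean of 10000 random lists matched on the number of regions per gene. HOX genes stand at 45.0%, with 18 genes against a matched mean of 10.6, and protocadherins at 48.8%, with 21 against 20.0.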

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

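The alternatives based on the difference above 33.3 points, the recomputed difference, the Mann-Whitney p, the lower group mean, the regions at 0, matched lists, distinct regions and coding members were chosen after seeing the data, and the cause of each change was not tested unless stated. The 2368 called regions became 1201 at a difference of at least 40 points, 3673 at q under 0.05, 1162 at q under 0.001 and 1446 with Benjamini-Hochberg adjustment of the Kolmogorov-Smirnov p. They stayed within 1.5 times that count at 10 points (3020), on autosomes (2319), when merged (2339), above 33.3 points (1708), with recomputed differences (2369) and with the Mann-Whitney p (3056). The share lower was 38.0% at 10 points, 26.6% with the Mann-Whitney p and 18.8% among the 351 called regions whose lower group mean exceeds 33.3%, so higher regions were the majority under each. The median genome-wide difference of 17.4 points compares with a mean of 11.4, a median of 3.30 without the regions at 0 in the control and 25% to 33.3% in the knockout, 4.17 also without their mirror, and 3.34 where both means exceed 0. The gene boundary share of called regions was 64.2% against 51.8% of the rest within 2000 bases (odds ratio 1.67), 42.9% against 31.4% for protein-coding genes only (1.65), 55.1% against 40.9% at 10 points (1.78) and 46.6% against 41.9% at 40 points (1.21); the wider boundary takes in more regions by construction. With other backgrounds chosen after seeing the data, the odds ratio of 1.57 became 1.32 without the regions at 0 in the control and 25% to 33.3% in the knockout, 2.55 against regions not called with a difference of at least 25 points (2.24 without those at 0) and 1.59 among regions of 10 or more sites. Of the 4 lists that passed, 0 did against matched lists and 2 over distinct regions (HOX and tumor suppressor genes, HOX only with its noncoding and readthrough members), and tumor suppressors also failed with gene bodies only (adjusted exact p = 0.0933). Counted over genes, the lymphoid list passed at 10 points (adjusted exact p = 0.0176) and at 40 points (0.0199) but not above 33.3 points (0.0606), and the erythroid list at 40 points (0.0461). Of the 84 named called regions, 64 remained called at 40 points, 53 at q under 0.001 and 61 with the adjusted Kolmogorov-Smirnov p. No paired analysis was possible because the table gives group means only. For the same reason the coverage minimum, the overdispersion settings, pooled reads and leaving out each replicate gave no value.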

Other observations

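All tests in this part were chosen after the result was seen except those on the site density of the regions at 0 in the control and on the direction of the protocadherin loci.

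Homeobox genes outside the HOX clusters also held many called regions in the authors' deposited table, in both directions. Of 137 measured, 69 had a called region, with 48 regions lower and 78 higher, and 13.3% of their 947 regions were called against 6.76% of other regions. Examples chosen after their values were seen are GBX1 (13.9% in the control to 91.2% in the knockout), PAX7 (29.5% to 99.4%), BSX (96.2% to 31.1%, a knockout mean within 3 points below 33.3%), SHOX (61.5% to 0.549%) and VAX2 (58.9% to 0.522%).

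The hypothesis that these genes hold called regions more often than genes with as many regions came from MNX1 and UNCX, among the 5 genes named for the most called regions (EN1 and ONECUT3 tie with the last of them), so it was found and tested on the same data. The list was also revised after its first result, and 6 versions were run. The first, whose symbol matching wrongly took genes such as ENO1 and PAXIP1, gave 74 of 163 genes and a two-sided permutation p of 0.0014 against 10000 matched lists. An interim matching that missed the LMX1 and PHOX2 genes gave 68 of 133 (permutation p = 0.0004), corrected matching with all PAX genes 72 of 142 (p = 0.0004), the list above, without PAX genes that lack a full homeodomain, 69 of 137 against a matched mean of 49.4 (p = 0.0002, the smallest these lists can give), that list without MNX1 and UNCX 67 of 135 (p = 0.0002), and also without EN1 and ONECUT3 65 of 133 (p = 0.0004). All 6 lie above their matched means, the p of 0.0014 is the one to weigh, and none is corrected for the choice of the list; the matched lists did not hold site density fixed, which is higher in called regions, so density may account for part of the excess.

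The clustered protocadherins had called regions in both directions, 3 higher and 3 lower. The gamma locus held 2 higher and 3 lower and the alpha and beta loci 1 higher and 0 lower (Fisher's exact p = 1), too few regions to decide whether the loci differ.

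The first pattern weighed is the 7348 regions at exactly 0 in the control and between 25% and 33.3% in the knockout, against 795 in the mirrored position. Incomplete conversion of 1 knockout library throughout stays open. Of the 15914 regions with a control mean under 5%, 32.5% (95% interval 31.8 to 33.3) had a knockout mean under 10%. That share argues against it only where the library in question covered these regions. If sites it did not cover were entered as 0, the same low means would follow, and coverage is unknown. For a gain at CpG-dense unmethylated regions in 1 library, the site density fell outside the bound set. Its median was 0.483 times (95% interval 0.46 to 0.494) that of regions with both means above 0 and under 10%. This does not decide against such a gain, because the pattern requires a control mean of exactly 0 and the compared regions one above 0. An exact 0 may itself select regions with few sites or reads, and coverage is unknown. Sites not covered in some libraries having been entered as 0, so that a methylated site seen in 1 of 3 libraries gives a mean of at most 33.3%, stays open: the ratio of 0.483 is within the bounds set for it, but so sparse a set is also 0.565 times as dense as regions with both means above 50% and resembles neither class. It remains a hypothesis, since levels of single libraries were not analysed here. At the genes fixed by name, such regions with the same number of sites had the same Mann-Whitney p whatever the knockout mean. With 5 sites it was 0.11984 at 26.667% and at 33.333%, and with 7 sites 0.064465 at 27.196% and at 33.333%. The tested points were thus ranked alike, but this does not show which libraries held the points above 0.

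The second pattern is that more called regions were higher than lower (67.8% higher), a share close to the 68.4% of all regions. A single knockout library moving the group mean stays open. Of called differences above 33.3 points, 68.1% were higher (95% interval 65.9 to 70.4). The weight of each library in a mean is not stated. Equal weights would cap the effect of 1 library at 33.3 points, but 1 library adding to other gains would give such a share too. Uncovered sites entered as 0 stay open: called higher regions had a control mean just below 33.3% 2.01 times as often as just above (181 against 90, 95% interval 1.55 to 2.62), against 1.03 and 1.46 at points 10 lower and 10 higher, but the step was steeper among called lower regions (6.15 times), where it would add losses. The bound of 2 set for the ratio of 2.01 is met by the value but not by its interval, and the interval was made the criterion after the value was seen. Of the 351 called regions whose lower group mean exceeds 33.3%, 285 were higher. These regions cannot decide the question, since a methylated site missed in 1 of 3 libraries can still give 66.7%. Means also step down past 66.7%: the bins just below and above it held 384 and 123 regions in the knockout, and 319 and 105 in the control. An exchange of the 2 group names stays open as well, because the 0 called regions at DNMT3B do not show which column is the edited line, and so does a biological effect of the knockout, which was not tested.

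In mitochondrial DNA, which has 3 regions in the table, the level was 30.4% in the knockout and 1.04% in the control at 11647 to 11715 (q = 0.075), 0% and 7.25% at 6616 to 6839 (q = 1), and 4.18% and 0.43% at 16410 to 16448 (q = 0.953).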
